A study of Mus musculus with 16 samples.

How the data were processed

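The data were 16 single-cell libraries made with droplet 3' chemistry (10x Chromium) from dissected ventral VMH tissue of adult female mice. Each library came as a matrix of UMI counts per gene and barcode that the authors deposited unnormalized. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 3.0 against mm10, the UCSC name of the GRCm38 assembly, and the matrix headers name software version 3.1.0. The annotation release is not given in the sources used here. Each matrix had 28000 features, of which 27998 are mouse genes and 2 are added sequences, a herpes virus vector and tdTomato, both with 0 UMIs in every library. Whether the barcodes had been filtered for doublets before deposit is not given in the sources used here. Gene symbols and identifiers are those of the matrices, and coordinates of named genes come from a GENCODE annotation of GRCm38 matched by identifier (150 of 150 genes). Counting by gene cannot separate reads of near-identical copies, so values of the tubulin and MHC class I genes can include reads shared with relatives.

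Groups were taken from the titles, which give reproductive state, behaviour and a replicate number. Collection dates in the labels fall into 8 sessions of dates up to 2 days apart. Control libraries of lactating and virgin females were collected together, the post-lactating libraries alone, and the behaviour groups in other sessions.

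Barcodes with at least 800 detected genes and under 15% mitochondrial UMIs were kept. Doublets were scored with Scrublet in scanpy 1.11.5, and the highest-scoring barcodes were removed at a rate proportional to the number of barcodes in the library, which took 6.64% to 10.43% of barcodes per library and left 7756 to 11679. Cells were clustered by the Leiden method on 30 principal components of 3000 variable genes (15 neighbours, resolution 1), and neurons again on 40 components at resolution 2. Immediate early, late activity-response, heat-shock, mitochondrial, ribosomal and X-inactivation genes were left out of clustering. Clusters were named from markers fixed for 19 cell classes, and a cluster without a clear class stayed unnamed. The share of neurons left unnamed was 27.23% to 52.13% per library, and an unnamed cluster outside the neurons, led by Hcrt and Pmch, held 6613 cells, 53.6% of them from virgin nonaggressive replicate 3 and 38.6% from lactating aggressive replicate 3 of the same session. VMH-like clusters were glutamatergic, had at least 5 VMH markers at or above the level of all neurons, an Nr5a1 or Fezf1 level of at least 1.5 times that of all neurons, and at least 0.5 of the median UMI count of neurons. These limits, and those on the distance between class scores (1.5 and -0.5 on the log2 scale), were set after the clusters were seen. The Esr1 rule of 2 times the level of all neurons, the markers, the gene lists, the comparisons, the rule for named genes and the alternatives were set before the data were examined.

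UMI counts were summed per library over the cells of a population, which ranged from 820940 to 6070657 UMIs in Esr1-rich VMH-like neurons. Libraries with under 20 cells of a population were left out. The sums were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the low-count filter filterByExpr by group, and the quasi-likelihood F test on a model of 7 group means over all 16 libraries, so that groups of 2 share an estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Lactating against virgin is the mean of the control and nonaggressive groups of one state minus that of the other. Printed levels are CPM per library over the population, with totals adjusted by the TMM factors (unadjusted for the means over the fallen genes and for levels used in the tests of the closing part), and log2 fold changes are those of edgeR. DESeq2 1.42.0 was run as a second tool. Gene lists (25, plus 12 of markers of other cells) were tested with camera at a preset correlation of 0.01 on voom values from limma 3.58.1, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. A list needed 3 measured genes. Counts of members adjusted over the list alone are given beside those over all genes. Shares of cells were compared with exact two-sided permutation tests.

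Named genes in Esr1-rich neurons are the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM, up to 4 members with the smallest p of each list that passed camera, and 12 fixed genes. In other classes 4 rises and 4 falls were named by that rule. Of the genes taken by the rule, 1 is not reported here. Genes named outside it are said to have been chosen after their values were seen, except where a list's called members, or all genes of a count of 6 or fewer, are given.

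The pipeline was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed 1.5-fold, 2-fold or 4-fold. The immediate early genes were shifted by log2 1 as well and are not counted as unchanged. For lactating against virgin Esr1-rich neurons it made 13 false calls among 12014 unchanged genes. Each gene was drawn independently from a single mean over all libraries, with no session effect or outlying library. The simulation therefore says nothing about false calls from such structure. The alternatives listed beforehand made 34 settings, of which 16 left out 1 library each. The others changed scaling, the tool, the low-count and barcode filters, doublet removal, cluster resolution, the minimum number of cells, the libraries in the fit, the averaging of behaviours, the definition of the population, and blocks for session and replicate number. A setting with low-UMI clusters added, a setting with cluster 41 alone, and tests within single neuron clusters were added after seeing the data. Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, and the R packages rtracklayer 1.62.0 and data.table (version 1.17.8). Pairs of libraries of a group differed by more than sampling noise in all 11 pairs (chi-square per degree of freedom 2.62 to 16.8 in Esr1-rich neurons), so no pair was treated as a library deposited more than once. Counting error depends on the UMIs and cells of a population (37 to 249 Esr1-rich cells per library), and the tests rest on the spread between libraries, which also holds that error.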

Results

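Single cells were profiled from the ventral part of the ventromedial hypothalamus (VMH), a hypothalamic nucleus whose estrogen receptor neurons take part in female social behaviour, dissected from adult female C57BL/6N mice. The data comprised 16 droplet libraries in 7 groups, defined by reproductive state and by the behaviour shown before collection. Lactating females formed a control group (n = 2), an aggressive group (n = 3) and a nonaggressive group (n = 2). Virgin females formed a control group (n = 2), a nonaggressive group (n = 3) and a mating group (n = 2), and 2 further control libraries came from post-lactating females. The labels do not say how many animals entered a library, so p-values measure the spread between libraries, which may be partly technical. The libraries held 226798 barcodes, from 11486 (post-lactating control replicate 2) to 18818 (virgin nonaggressive replicate 1). Each held between 52923987 and 108364921 unique molecular identifiers (UMIs), with medians of 2714 to 5470 UMIs per barcode.

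After filtering, 150362 cells were clustered, and 47921 of them fell in clusters named as neurons. Clustered again, these held some clusters led by genes of other cells, such as cluster 39 (C1qb, C1qa, C1qc) and cluster 37 (Slc1a3, Slc4a4, Gm3764). Those stayed unnamed and are counted in shares of neurons. VMH markers were carried by 10 numbered clusters, and 2 of these had an Esr1 level at least 2 times that of all neurons, cluster 17 (Rasl11a, Samd9l, Gadd45a) and cluster 41 (Chst9, Esr1, Dgkk). Together they formed the Esr1-rich VMH-like neurons, 2163 cells. The number of these cells ran from 37 (lactating control replicate 1) to 249 (virgin nonaggressive replicate 2), and their UMIs per library from 820940 (virgin mating replicate 1) to 6070657 (virgin control replicate 2). Cluster 17 held 0% of the Esr1-rich cells in all 7 lactating libraries, 0% (replicate 3) to 93.12% (replicate 1) in the virgin nonaggressive group, and 8.62% and 66.81% in the post-lactating libraries. Its leading genes are among those that differed with lactation, so its share is not read as a change in cell number. Levels are given as CPM, the UMI count scaled to the TMM-adjusted total of the population in each library, and differences as log2 fold changes.

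The first question was how the Esr1-rich neurons of lactating females differ from those of virgins. Over the control and nonaggressive behaviours that both states share (n = 4 against n = 5 libraries), Pappa, which encodes a protease that cleaves IGF-binding proteins, rose from 1.69 ± 1.55 to 24.4 ± 6.35 CPM (SD), a log2 fold change of 4.20 (SE 0.34, adjusted p = 7.64e-06). Tuba8, an alpha-tubulin, rose from 1.75 ± 1.26 to 26.1 ± 6.35 CPM (log2 4.09, SE 0.36, adjusted p = 1.48e-05). Kcnc2, which encodes the voltage-gated potassium channel subunit Kv3.2, rose from 52.8 ± 14.1 to 259 ± 18.9 CPM (log2 2.31, adjusted p = 2.87e-05). Pgr, the progesterone receptor, fell from 275 ± 127 to 60.5 ± 14.2 CPM (log2 -2.18, adjusted p = 0.00385), while Esr1 itself was at 461 ± 32.4 CPM in virgin and 427 ± 39.4 CPM in lactating libraries (log2 -0.11, adjusted p = 0.759). In all, 190 genes rose and 208 fell of 12437 tested with edgeR, 1869 had an unadjusted p under 0.05, and DESeq2 called 505.

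In the GRCm38 assembly, Pappa (ENSMUSG00000028370) lies on chromosome 4 from 65124174 to 65357509, Tuba8 (ENSMUSG00000030137) on chromosome 6 from 121210696 to 121226854, and Kcnc2 (ENSMUSG00000035681) on chromosome 10 from 112271121 to 112467024. Pgr (ENSMUSG00000031870) lies on chromosome 9 from 8899833 to 8968611 and Samd9l (ENSMUSG00000047735) on chromosome 6 from 3372257 to 3399572. All 5 are annotated as protein-coding, and values are counts over the whole gene.

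The other genes with the largest rises were Cacng5, a transmembrane regulator of AMPA receptors (44.9 ± 8.73 against 6.43 ± 2.33 CPM, log2 2.78), Traf3ip3 (log2 2.35), the cholesterol exporter Abca1 (log2 2.32), the Notch coactivator Maml3 (log2 2.18) and Socs1, a suppressor of cytokine signalling (log2 2.14, adjusted p = 0.00246). The largest falls were of Samd9l, an interferon-inducible gene, from 63.1 ± 43.9 to 0.50 ± 0.40 CPM (log2 -6.62, SE 1.23, adjusted p = 0.00752), Rasl11a (log2 -5.21), Phf21b (log2 -4.60), Cd24a (log2 -3.44), Gadd45a, a growth-arrest and DNA-damage gene (log2 -3.11), Col12a1 (log2 -2.95), the opioid precursor Pdyn (log2 -2.78) and Mad2l1 (log2 -2.57). The fallen genes varied widely among virgin libraries, and virgin nonaggressive replicate 3 held them near the lactating level, with a mean log2 CPM (unadjusted totals) of 2.39 against 1.95 to 2.50 in lactating libraries. Of the other genes followed in every comparison, Oxtr, the oxytocin receptor, rose (log2 0.85, adjusted p = 0.0286), as did Prlr, the prolactin receptor (log2 0.48, adjusted p = 0.0318). Cckar, a cholecystokinin receptor, fell (log2 -1.36, adjusted p = 0.00453). Tac1, the substance P precursor, stood at 1791 ± 252 against 1009 ± 406 CPM (log2 0.81, adjusted p = 0.159), and Npy2r at 10.2 ± 2.61 against 10.5 ± 2.71 CPM.

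**Figure D1:**
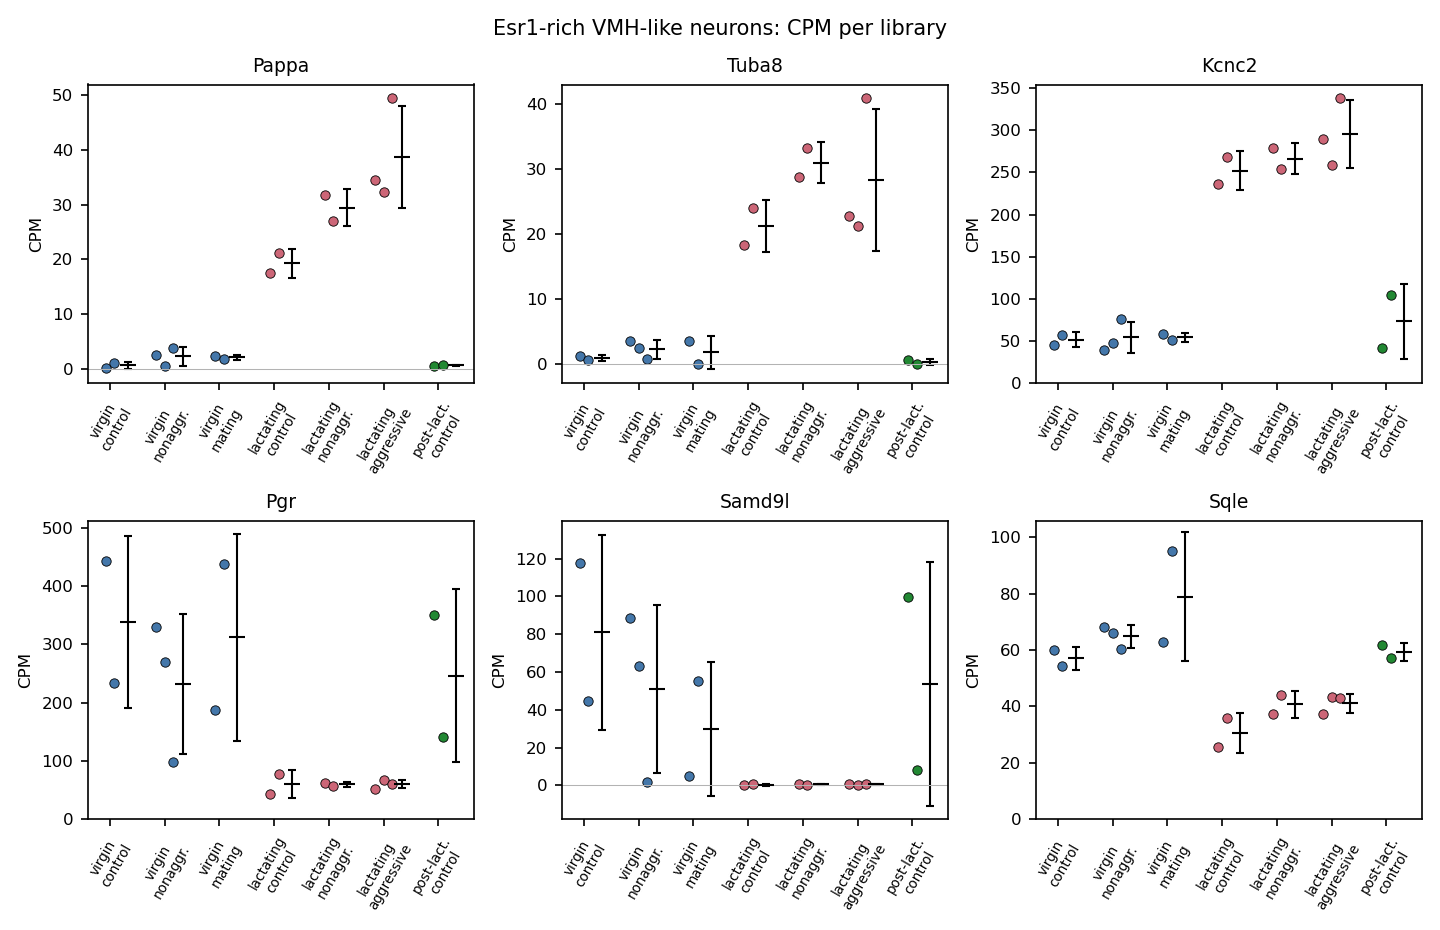
CPM of Pappa, Tuba8, Kcnc2, Pgr, Samd9l and Sqle in Esr1-rich VMH-like neurons, on linear axes that include 0, by group; points are libraries, and the black tick and bar are the group mean and SD. Pappa averaged 24.4 CPM over the 4 lactating libraries of the comparison and 1.69 CPM over the 5 virgin ones, and Pgr averaged 60.5 and 275 CPM.

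Of the gene lists fixed beforehand, the sterol synthesis list fell as a group. Of its 17 measured members 0 rose and 8 fell over all genes, and 13 fell when adjusted over the list alone (median log2 -0.55, camera adjusted p = 2.64e-13). This call held with an estimated correlation (adjusted p = 0.0108). Examples were Idi1 (log2 -1.09), Hmgcs1 (log2 -0.75) and Sqle, squalene epoxidase (log2 -0.75). Of 9 prolactin and STAT5 response genes 4 rose and 1 fell, or 5 and 2 adjusted over the list alone (median log2 0.48, camera adjusted p = 0.0137, but adjusted p = 0.107 with an estimated correlation). Those that rose were Socs1, Socs2, Prlr and Igf1, insulin-like growth factor 1 (log2 1.60), and the one that fell was Stat5a, a transcription factor of prolactin signalling (log2 -2.91). Of 9 estrogen-responsive genes 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (median log2 -0.41, camera adjusted p = 0.0343, adjusted p = 0.107 with an estimated correlation), with Pgr, Greb1 (log2 -1.45), Cckar and Nrip1 (log2 -1.12) down and Oxtr up. Of 10 glucocorticoid response genes 0 rose and 2 fell, and 5 fell adjusted over the list alone (median log2 -0.60, camera adjusted p = 0.00238, adjusted p = 0.0651 with an estimated correlation). The 2 were Fkbp5, a cochaperone of the glucocorticoid receptor (log2 -2.51), and the kinase Sgk1 (log2 -1.43).

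Of 22 immediate early genes, which neurons transcribe within minutes of activity, 0 rose and 2 fell, Klf4 (log2 -4.48) and Egr1 (log2 -1.41), and 7 fell adjusted over the list alone (median log2 -0.91, camera adjusted p = 0.00143, adjusted p = 0.202 with an estimated correlation). Of 6 interferon and MHC class I genes 1 rose, B2m (log2 1.14), and 4 rose adjusted over the list alone (median log2 0.57, camera adjusted p = 0.0125, adjusted p = 0.107 with an estimated correlation). Of 17 unfolded protein response genes 1 fell, Sdf2l1 (log2 -0.89), and 1 adjusted over the list alone (median log2 -0.22, camera adjusted p = 0.00186, adjusted p = 0.235 with an estimated correlation). Among 15 dissociation and heat-shock genes (median log2 -0.18, camera adjusted p = 0.0343) and 13 mitochondrially encoded genes (median log2 -0.34, camera adjusted p = 0.00186) 0 passed over all genes by edgeR. Those calls too were lost with an estimated correlation, at adjusted p = 0.107 and 0.482.

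The 15 lists not called had medians from -0.35 to 0.61 and a smallest adjusted p of 0.0508. They were late activity-response genes, hormone receptors, neuropeptides, neuropeptide and monoamine receptors, potassium and HCN channels, sodium and calcium channels, glutamate receptors, GABA receptors, circadian clock genes, nuclear oxidative phosphorylation genes, ribosomal proteins, synaptic vesicle genes, myelin genes, reactive astrocyte genes and homeostatic microglia genes. Among the 33 neuropeptide and monoamine receptors, 8 rose and 4 fell. Examples, chosen after their values were seen, were Tacr3, a tachykinin receptor (log2 4.38), Htr2a, a serotonin receptor (log2 2.01), and the melanocortin receptor Mc3r (log2 -2.76). Markers of the 6 other kinds of cell that could be measured (choroid plexus, arcuate neurons, astrocytes, oligodendrocytes, microglia and GABAergic neurons) had medians from -0.83 to -0.10 and a smallest adjusted p of 0.489. In simulated data for this comparison, over 12227 genes, 23.9% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold were recovered.

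The number of changed genes depended on the libraries and cells used. It was 137 without virgin control replicate 1, 162, 166, 176 and 201 without lactating control replicate 2, nonaggressive replicate 1, nonaggressive replicate 2 and control replicate 1, and 826 without virgin nonaggressive replicate 3. With the collection session as a block it was 738, of which 373 were among the 398. Pappa (log2 4.28) and Pgr (log2 -2.23) passed there as well, B2m (log2 1.09, adjusted p = 0.0571) did not, and Tac1 (log2 1.10, adjusted p = 0.0067) and Fos (log2 -1.91, adjusted p = 0.0381) did. Barcodes chosen by Slc17a6 and Esr1 UMIs in place of clusters gave 217 genes, cluster 41 alone 163, and the fit without the low-count filter 1042, 995 of them among the genes tested here. With those barcodes Abca1 (log2 0.50, adjusted p = 0.1), Socs1, Igf1, B2m, Oxtr, Prlr, Sdf2l1, Idi1, Nrip1, Cckar, Egr1, Sgk1, Greb1, Fkbp5, Pdyn, Stat5a, Col12a1, Cd24a, Klf4 and Rasl11a did not pass. Within cluster 41 Samd9l, Rasl11a, Gadd45a, Phf21b, Cd24a, Pdyn, Pgr (log2 -0.73, adjusted p = 0.482), Cckar, Oxtr, Prlr, Sqle, Idi1, Sdf2l1, Nrip1, Sgk1, Greb1 and Fkbp5 did not pass, and Mad2l1 (log2 0.48) and Col12a1 (log2 0.54) changed sign. That setting leaves out the other Esr1-rich cluster, which is led by Rasl11a, Samd9l and Gadd45a. The cluster left out held 0% of the Esr1-rich cells in lactating libraries and up to 93.12% in virgin ones. Virgin cells were thus in effect selected on fallen genes, so a lost call or changed sign of a fallen gene there decides little. Pappa, Tuba8, Cacng5, Traf3ip3, Abca1, Kcnc2, Maml3, Socs1, Pgr, Phf21b, Klf4, Hmgcs1 and Sqle passed in all 16 fits that left out a library, and the other genes reported here by the fixed rule did not. Samd9l (log2 -8.49, adjusted p = 0.0735), Idi1 (log2 -0.92, adjusted p = 0.0616) and Cckar (log2 -1.21, adjusted p = 0.0639) missed the threshold without lactating control replicate 2 alone. Pdyn missed it in 12 of the 16 fits, Sdf2l1 in 9, Col12a1 in 8, Oxtr, Prlr and Sgk1 in 7, B2m in 6, and Nrip1, Egr1, Fkbp5, Stat5a, Cd24a, Rasl11a, Igf1, Greb1, Mad2l1 and Gadd45a in 2 to 5.

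The next question was what remained after lactation. Against lactating controls (n = 2 against n = 2), post-lactating libraries had lower Tuba8 (0.326 ± 0.461 against 21.2 ± 3.99 CPM, log2 -5.81, adjusted p = 0.00603) and lower Pappa (0.699 ± 0.0662 against 19.3 ± 2.60 CPM, log2 -4.74, adjusted p = 0.00603). Cacng5 (log2 -2.47), the homeobox gene Prox1 (log2 -2.42), Traf3ip3 (log2 -2.15), Maml3 (log2 -2.09), the contactin Cntn5 (log2 -2.09) and the apoptosis inhibitor Bcl2 (log2 -2.02) were the other largest falls. Vav3, a guanine nucleotide exchange factor (log2 1.43), Gm26905 (log2 1.91) and Smim18 (log2 1.04) rose. Pgr averaged 246 ± 149 against 61.2 ± 24.2 CPM, a difference that did not pass (log2 1.95, adjusted p = 0.266). By edgeR 3 genes rose and 19 fell, with 1141 at an unadjusted p under 0.05 and 47 by DESeq2.

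The sterol synthesis list rose against lactating controls, with 9 of its members up when adjusted over the list alone and 0 over all genes (median log2 0.53, camera adjusted p = 9.16e-09, and adjusted p = 0.0438 with an estimated correlation). The prolactin and STAT5 response list had 4 members down when adjusted over the list alone, Socs1 (log2 -1.80), Socs2 (log2 -1.59), Igf1 (log2 -1.52) and Cish (log2 -1.29), and a median of -0.30 (camera adjusted p = 0.0178, adjusted p = 0.131 with an estimated correlation). Immediate early genes (median log2 0.75), neuropeptide and monoamine receptors (-0.26), unfolded protein response genes (0.22) and nuclear oxidative phosphorylation genes (0.33) passed camera, each lost with an estimated correlation, where the smallest adjusted p was 0.131. The other 18 lists had medians from -0.19 to 0.64 and a smallest adjusted p of 0.0804. Simulated data for this comparison, over 12239 genes, gave a recovery of 4.48%, 31.3% and 80.3% at 1.5-fold, 2-fold and 4-fold.

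Against virgin controls, 0 of 12437 genes passed in post-lactating libraries by edgeR or by DESeq2, with 706 at an unadjusted p under 0.05 and a smallest adjusted p of 0.754. Without the low-count filter 82 passed, 79 of them among the genes tested here. Recovery in simulated data over 12216 genes was 1.49%, 25.4% and 86.4% at those folds, so small changes were mostly not detectable at this depth and number of libraries. Neuropeptides (median log2 0.41), glutamate receptors (-0.14) and nuclear oxidative phosphorylation genes (0.34) passed camera and were lost with an estimated correlation, where the smallest adjusted p was 0.614. Astrocyte markers were higher (median log2 0.60, camera adjusted p = 0.000106) and microglia markers lower (median log2 -0.91, camera adjusted p = 0.00542), both at adjusted p = 0.0967 with an estimated correlation. The other 21 lists had medians from -0.44 to 0.71 and a smallest adjusted p of 0.0523. Between virgin and lactating nonaggressive females, whose libraries enter neither post-lactating contrast, 54 genes rose and 20 fell. The spread behind these calls was estimated over all 16 libraries, so the choice of genes is not fully separate from those contrasts. Of these 74 genes, 59.5% (44 genes, exact binomial 95% interval 47.4 to 70.7 over genes, which are not independent) had the same sign in post-lactating against virgin controls. The median log2 fold change of the risen genes went from 1.59 to 0.16, and that of the fallen genes from -1.23 to -0.02. Against lactating controls, 72 of the 74 (97.3%) had the opposite sign. The 74 calls became 16 and 17 without lactating nonaggressive replicates 1 and 2, 39, 27 and 502 without virgin nonaggressive replicates 1, 2 and 3, and 47 without lactating aggressive replicate 2. Falls outnumbered rises without virgin nonaggressive replicate 3 (317 and 185), without the low-count filter (470 and 220), with a replicate block (190 and 144) and by DESeq2 (82 and 79). The share with the same sign ran from 38.3% to 72.5% without post-lactating control replicate 2 or 1, and was 90.9% of 11 genes in fits of only the groups compared and 36.4% of 11 over barcodes chosen by Slc17a6 and Esr1 UMIs.

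The calls against lactating controls numbered 0 without post-lactating control replicate 1, 1 and 6 without lactating control replicates 2 and 1, 10 without lactating aggressive replicate 1 or 2, 14 without lactating nonaggressive replicate 1 or 2, and 37 without virgin nonaggressive replicate 3. Pappa missed the threshold without post-lactating control replicate 1 (log2 -4.65, adjusted p = 0.131) or lactating control replicate 2 (log2 -4.57, adjusted p = 0.129). Of the other genes, Cntn5, Traf3ip3 and Maml3 missed it in 11, 9 and 8 of the 16 fits that left out a library, and Gm26905, Smim18, Vav3, Bcl2, Prox1, Tuba8 and Cacng5 in 1 to 5. Each post-lactating library had a collection session of its own, so session and state cannot be told apart there. Barcodes chosen by Slc17a6 and Esr1 UMIs gave 12 genes, cluster 41 alone 38, and the fit without the low-count filter 409, 404 of them among the genes tested here.

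**Figure D2:**
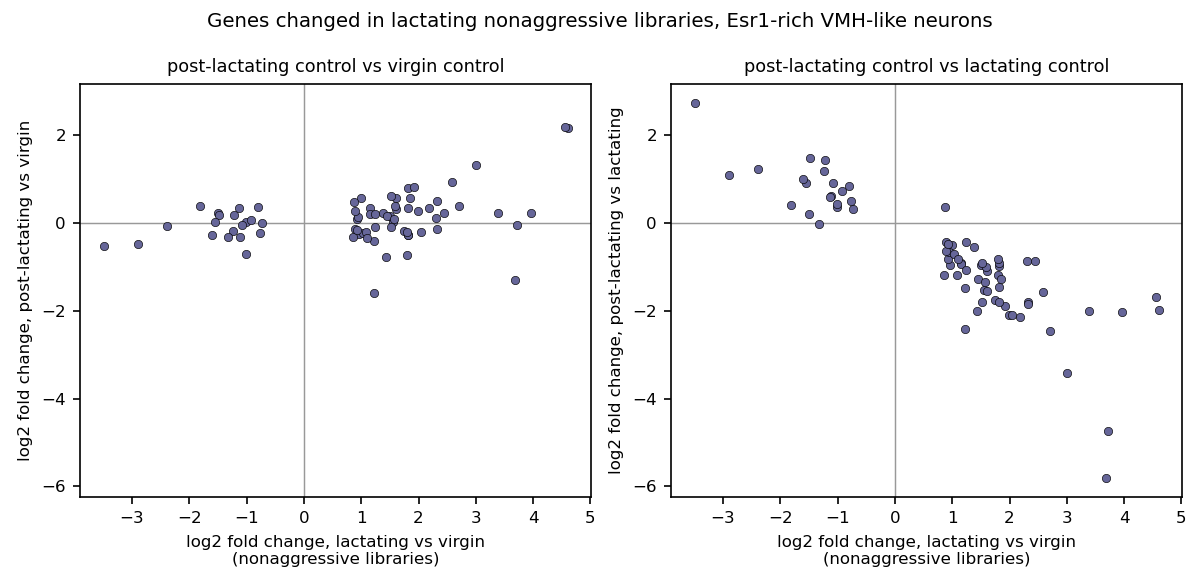
Log2 fold change of 74 genes called between lactating and virgin nonaggressive libraries (x axis) against their log2 fold change in post-lactating against virgin control libraries (left, y axis) and against lactating control libraries (right, y axis); each point is a gene. On the left 44 genes have the same sign on both axes, and on the right 72 have opposite signs.

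Mating was compared with the 2 other virgin groups to ask which genes follow that behaviour. Fos, a transcription factor gene used as a marker of recent neuronal activity, was at 86.4 ± 36.4 CPM after mating (n = 2), 5.80 ± 6.75 CPM in virgin controls (n = 2) and 4.16 ± 2.16 CPM in the nonaggressive group (n = 3). It rose against both (log2 3.83, adjusted p = 0.0252, and log2 4.34, adjusted p = 0.00451). Egr1, another activity-induced transcription factor, reached 179.9 ± 88.2 CPM, against 25.9 ± 18.3 in controls (log2 2.77, adjusted p = 0.0233) and 21.4 ± 2.64 in the nonaggressive group (log2 3.06, adjusted p = 0.00224). Junb, a partner of Fos, rose likewise (log2 2.54 and 2.69, adjusted p = 0.0168 and 0.00224). Esr1, Pgr and Npy2r differed by log2 0.06, -0.11 and 0.24 from controls, all far from the threshold.

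Against controls 5 genes rose and 0 fell (1484 at an unadjusted p under 0.05, 69 by DESeq2), the other 2 being Fosl2 (log2 4.14) and Vav3 (log2 1.37). Against the nonaggressive group 6 rose and 0 fell (888 at an unadjusted p under 0.05, 12 by DESeq2), the other 3 being Rrad, a small GTPase (log2 1.78), Ddx10 (log2 1.23) and Dnajc1 (log2 1.04). Of 22 immediate early genes 4 rose against controls and 13 adjusted over the list alone (median log2 1.74, camera adjusted p = 4.24e-12, but adjusted p = 0.0795 with an estimated correlation). Against the nonaggressive group 3 rose and 12 adjusted over the list alone (median log2 1.39, camera adjusted p = 1.30e-19, and adjusted p = 0.0151 with an estimated correlation). Fosb (8.42 ± 0.0312 CPM) and Nr4a1 (12.8 ± 7.51 CPM) did not pass over all genes in either comparison. In GRCm38, Fos (ENSMUSG00000021250) lies on chromosome 12 from 85473890 to 85477273 and Egr1 (ENSMUSG00000038418) on chromosome 18 from 34859823 to 34864984.

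The mating libraries also had lower mitochondrially encoded genes, with medians of -1.10 against controls and -1.0 against the nonaggressive group (camera adjusted p = 3.04e-12 and 3.17e-14, adjusted p = 0.181 and 0.135 with an estimated correlation). Adjusted over the list alone, 10 and 8 of these genes fell. The other lists that passed camera against controls were prolactin and STAT5 response (median log2 -0.66), neuropeptides (0.31), sterol synthesis (0.26), nuclear oxidative phosphorylation (0.38) and interferon and MHC class I genes (0.40), all lost with an estimated correlation. Choroid plexus markers were lower (median log2 -0.73, camera adjusted p = 0.0242, adjusted p = 0.105 with an estimated correlation). Against the nonaggressive group the others were late activity-response (0.36), prolactin and STAT5 response (-0.48), sterol synthesis (0.26), ribosomal protein (-0.15) and interferon and MHC class I genes (0.57), all lost in the same way. The remaining 17 lists in each comparison had smallest adjusted p values of 0.0551 and 0.11.

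The calls after mating rested on few libraries. Against controls they numbered 0 without virgin control replicate 1 or mating replicate 1, 3 without virgin control replicate 2, 9 without nonaggressive replicate 3 and 19 without mating replicate 2. Against the nonaggressive group they numbered 0 without mating replicate 1, 2 and 3 without nonaggressive replicates 2 and 1, and 10 without nonaggressive replicate 3. Without mating replicate 1, Fos was at log2 3.33 (adjusted p = 0.432) against controls and 3.83 (adjusted p = 0.0926) against the nonaggressive group. It also missed the threshold without virgin control replicate 1 (adjusted p = 0.0661), lactating control replicate 1 (adjusted p = 0.0518) or lactating aggressive replicate 1 (adjusted p = 0.0506) against controls, and without nonaggressive replicate 2 (adjusted p = 0.0606) against that group. Dnajc1, Ddx10 and Rrad missed it in 12, 7 and 3 of the 16 fits. Barcodes chosen by Slc17a6 and Esr1 UMIs gave 1 and 0 genes, cluster 41 alone 10 and 3, and fits without the low-count filter 335 and 172, of which 329 and 167 were among the genes tested here. No mating library shared a session with a virgin control, so session and behaviour cannot be told apart in that comparison. With session as a block, mating against nonaggressive gave 6 genes, 5 of them shared, and an immediate early gene median of 1.67 (camera adjusted p = 1.30e-17, adjusted p = 0.165 with an estimated correlation). Simulated data over 12225 genes gave a recovery of 5.97%, 25.4% and 78.8% at 1.5-fold, 2-fold and 4-fold against controls, and 4.48%, 26.9% and 75.8% over 12227 genes against the nonaggressive group.

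**Figure D3:**
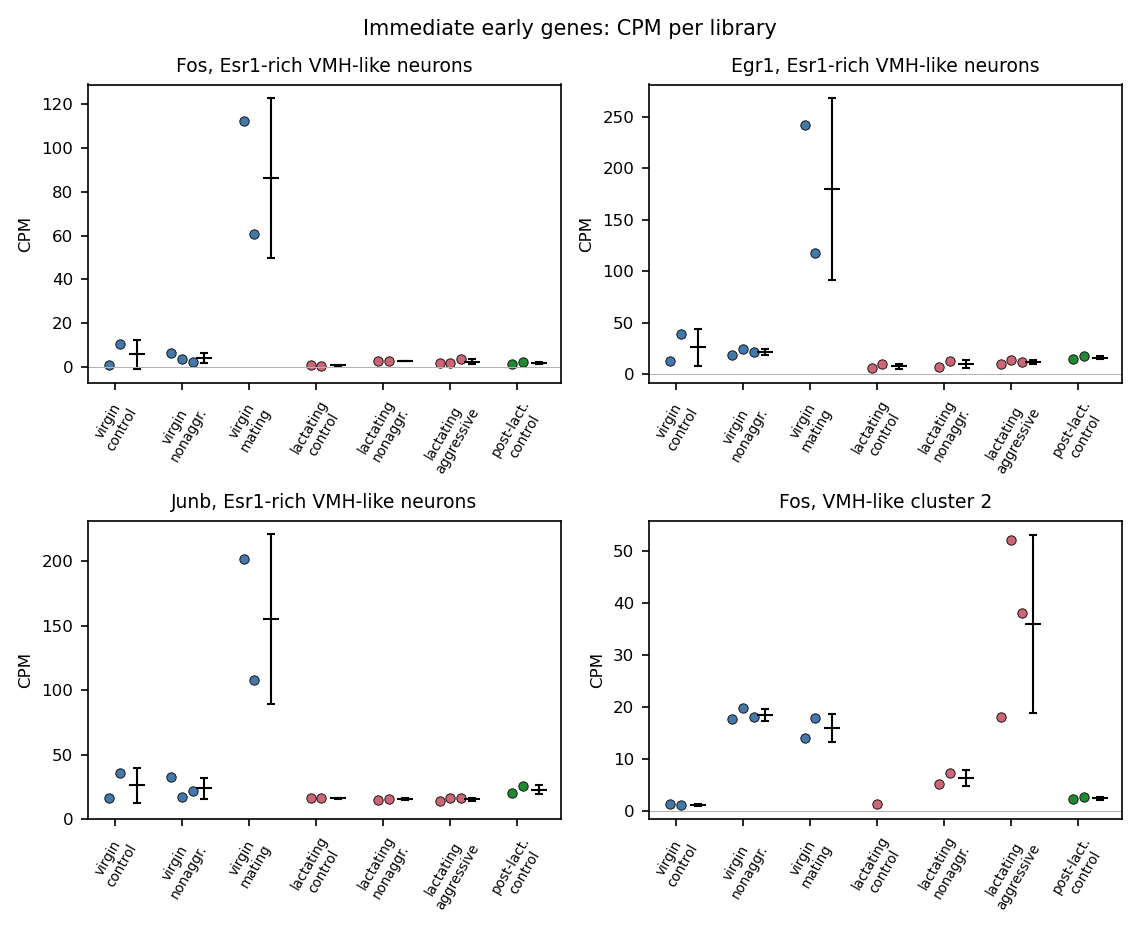
CPM of Fos, Egr1 and Junb in Esr1-rich VMH-like neurons and of Fos in neuron cluster 2, on linear axes that include 0, by group; points are libraries, and the black tick and bar are the group mean and SD. In Esr1-rich neurons Fos averaged 86.4 CPM after mating and 2.41 CPM after lactating aggression, and in cluster 2 it averaged 15.9 and 36.0 CPM.

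Aggression was compared within lactating females to ask which genes follow attack. In Esr1-rich neurons Fos was at 2.41 ± 1.10 CPM in aggressive (n = 3), 2.70 ± 0.0422 in nonaggressive (n = 2) and 0.819 ± 0.140 in control libraries (n = 2), and neither Fos nor Egr1 passed (log2 1.62 and 0.51 against controls, both adjusted p = 1). By edgeR 0 of 12437 genes changed in aggressive libraries against controls (276 at an unadjusted p under 0.05, 0 by DESeq2), 0 against the nonaggressive group (231 and 0), and 0 between nonaggressive and control libraries (625 and 1). The immediate early gene medians were 0.40, 0.01 and 0.26, with adjusted p values of 0.204, 0.643 and 0.578. Without nonaggressive replicate 2, 1 gene passed for aggressive against nonaggressive libraries. Fits without the low-count filter gave 26, 32 and 84 genes for the 3 comparisons, of which 24, 29 and 83 were among the genes tested here. Recovery in simulated data at 2-fold and 4-fold was 38.8% and 84.8% of genes against controls over 12231 genes, 53.7% and 86.4% against the nonaggressive group over 12221 genes, and 38.8% and 80.3% between nonaggressive and control over 12239 genes.

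Unfolded protein response genes (median log2 0.22, camera adjusted p = 0.000687), such as Pdia6 (128 ± 5.98 against 89.8 ± 4.99 CPM), and nuclear oxidative phosphorylation genes (0.14) passed camera in aggressive against control libraries, at adjusted p = 0.688 with an estimated correlation. Against the nonaggressive group GABA receptors (0.17) and mitochondrially encoded genes (0.32) passed, at adjusted p = 0.425 with an estimated correlation, and astrocyte markers were higher (0.42, camera adjusted p = 0.0382, adjusted p = 0.502 with an estimated correlation). Between nonaggressive and control libraries circadian clock (-0.22), unfolded protein response (0.17), nuclear oxidative phosphorylation (0.26), mitochondrially encoded (-0.53), synaptic vesicle (-0.12) and interferon and MHC class I genes (0.49) passed, as did GABAergic markers (1.18). All 7 calls were lost with an estimated correlation, where the smallest adjusted p was 0.529. The remaining 22, 22 and 18 lists had smallest adjusted p values of 0.204, 0.163 and 0.0638.

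In virgin nonaggressive against virgin control libraries (n = 3 against n = 2), 0 of 12437 genes passed by edgeR, with 895 at an unadjusted p under 0.05 and 18 by DESeq2, and 2 passed without nonaggressive replicate 3. Without the low-count filter 208 passed, 201 of them among the genes tested here. The immediate early gene median was -0.30 (adjusted p = 0.316) and became 0.49 (adjusted p = 3.16e-06) over barcodes chosen by Slc17a6 and Esr1 UMIs. Without virgin control replicate 1 it was -0.18 and passed. Neuropeptides (0.50), nuclear oxidative phosphorylation genes (0.38), ribosomal proteins (0.13) and astrocyte markers (0.56) passed camera, at a smallest adjusted p of 0.27 with an estimated correlation. The other 21 lists had medians from -0.30 to 1.20 and a smallest adjusted p of 0.109. Recovery in simulated data over 12200 genes was 49.3% at 2-fold and 87.9% at 4-fold. Every comparison of a behaviour with controls is confounded with collection session, because no control library shared a session with a behaviour group. Aggressive against nonaggressive libraries gave 0 genes with session as a block.

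Single VMH-like clusters were compared next, to ask which neurons carry an activity signal. In cluster 2 (Necab1, Adarb2, Npy2r), which carries the neuropeptide Y receptor gene Npy2r, Fos was at 36.0 ± 17.1 CPM in lactating aggressive libraries (n = 3), 6.23 ± 1.53 in nonaggressive (n = 2) and 1.40 in the 1 lactating control library that had at least 20 cells. Fos rose in aggressive against nonaggressive libraries (log2 2.56, adjusted p = 0.0198), and the level in the lone control library is given as a value with no test. Fos in cluster 2 also rose after mating (15.9 ± 2.67 CPM) and in the virgin nonaggressive group (18.4 ± 1.11 CPM) against virgin controls (1.19 ± 0.2045 CPM), by log2 3.75 (adjusted p = 0.0304) and 3.92 (adjusted p = 0.00573). In cluster 41 Fos rose after mating against controls (log2 2.85, adjusted p = 0.0396) and against the nonaggressive group (log2 4.39, adjusted p = 0.00551). Virgin nonaggressive replicate 1, with under 20 cells of cluster 41, was left out there. The adjusted p values of Fos are over the genes of a single cluster and comparison, not over clusters or comparisons. Over the whole immediate early gene list, 0 of 6 clusters passed fry's directional test over 36 tests, and 8 tests had an unadjusted p under 0.05. The smallest adjusted p was 0.0842, in cluster 4 (Dlk1, Arhgap36, Pcdh11x) for mating and for virgin nonaggressive against control, and cluster 2 had a median of 1.54 for aggressive against the lone control library and 0.83 against the nonaggressive group (adjusted p = 0.203). Clusters 2 and 4 passed without lactating aggressive replicate 1, clusters 4 and 41 without virgin mating replicate 2, and cluster 4 without virgin nonaggressive replicate 1 or with at least 50 cells per library.

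Other cell classes were compared between lactating and virgin libraries over the same behaviours. In GABAergic neurons (378 to 1325 cells per library) 54 genes rose and 3 fell of 14835 tested. Foxq1, a forkhead transcription factor gene, rose from 4.47 ± 3.12 to 40.6 ± 12.1 CPM (log2 3.08, adjusted p = 0.00433), the adhesion receptor Adgrg6 from 7.99 ± 2.20 to 43.7 ± 5.465 CPM (log2 2.47, adjusted p = 0.00226), Grp, gastrin-releasing peptide, by log2 2.14 and the kinase Prkch by log2 2.12. Sema5a, a guidance factor (log2 -0.61), and Sgcd (log2 -0.52) fell. Of these Grp, Sema5a and Sgcd missed the threshold in 11, 13 and 13 of the 16 fits that left out a library. Foxq1 (ENSMUSG00000038415) lies on chromosome 13 from 31556134 to 31560976 in GRCm38. Foxq1 and Adgrg6 are among the leading genes of GABAergic cluster 22 (Slc18a2, Gm4847, Coch), which made up 8.61 ± 3.40% of GABAergic cells in lactating (n = 4) and 5.64 ± 2.0% in virgin libraries (n = 5).

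The edgeR count in GABAergic neurons compares with 1009 genes at an unadjusted p under 0.05 and 135 by DESeq2. It was 160 without the low-count filter, 137 with session as a block, 52 of them shared, 1 in lactating control against virgin control alone, 20 without lactating nonaggressive replicate 1, 24 without virgin control replicate 1, and 35 and 37 without lactating control replicates 2 and 1. Of 25 lists 10 passed camera, with the lowest p for sterol synthesis genes (median log2 -0.20, camera adjusted p = 7.63e-07), and all were lost with an estimated correlation, where the smallest adjusted p was 0.339. Arcuate neuron markers were higher (median log2 0.94, camera adjusted p = 0.0341, adjusted p = 0.307 with an estimated correlation), and choroid plexus (0.39) and GABAergic markers (-0.24) passed camera at adjusted p = 0.0435 and were lost with an estimated correlation (adjusted p = 0.307). Simulated data over 14621 genes gave a recovery of 43.3%, 79.1% and 98.5% at 1.5-fold, 2-fold and 4-fold.

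In oligodendrocyte precursors the unfolded protein response list fell, with 11 of 17 members down when adjusted over the list alone and 0 over all genes (median log2 -0.37, camera adjusted p = 5.45e-23). This call held with an estimated correlation (adjusted p = 0.00989), while the other 6 lists past camera there were lost (smallest adjusted p = 0.0547), and arcuate neuron markers were higher there (median log2 0.57, camera adjusted p = 0.0461, adjusted p = 0.681 with an estimated correlation). By edgeR 0 genes passed in astrocytes (627 at an unadjusted p under 0.05, 5 by DESeq2), 0 in oligodendrocytes (374 and 3), 0 in oligodendrocyte precursors (235 and 0) and 0 in microglia (327 and 0). Fits without the low-count filter gave 11, 40, 22 and 26 genes in these classes. In astrocytes 1 gene passed without virgin control replicate 2, and in microglia 1 without lactating nonaggressive replicate 2. In endothelial cells Gm9946 rose, from 31.4 ± 9.21 to 70.9 ± 7.05 CPM (log2 1.14, adjusted p = 0.0256), with 388 genes at an unadjusted p under 0.05 and 2 by DESeq2. It was the single gene called, and the call was lost in 11 of the 16 fits that left out a library, all but those without lactating aggressive replicate 1 or 2, virgin control replicate 2 or a post-lactating library. Without lactating aggressive replicate 1, 2 genes passed, and without the low-count filter 40. Astrocytes had 11 lists past camera, including immediate early genes (median log2 -0.27) and synaptic vesicle genes (-0.19), oligodendrocytes 6, including heat-shock genes (-0.21), microglia 5 and endothelial cells 8, with smallest adjusted p values of 0.183, 0.111, 0.661 and 0.148 once the correlation was estimated. GABAergic markers were lower (-0.45, camera adjusted p = 0.00804) and tanycyte and ependymal markers higher (0.47, camera adjusted p = 0.00315) in astrocytes, both at adjusted p = 0.388 with an estimated correlation. Endothelial markers were lower in microglia (-0.42, camera adjusted p = 0.0362, adjusted p = 0.264 with an estimated correlation), and microglia markers in endothelial cells (-0.84, camera adjusted p = 1.68e-07, adjusted p = 0.202 with an estimated correlation). Recovery at 2-fold in simulated data was 85.1% in astrocytes over 14958 genes, 73.1% in oligodendrocytes over 12747, 83.6% in precursors over 13410, 74.6% in microglia over 11205 and 71.6% in endothelial cells over 11233.

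The makeup of the tissue was compared last. Of 12 cell class shares, 0 differed between lactating (n = 4) and virgin (n = 5) libraries in exact two-sided permutation tests over 126 splits, with 0 at an unadjusted p under 0.05 and a smallest p of 0.143. Astrocytes made up 30.6 ± 2.51% and 29.9 ± 4.40% of cells. Of 10 VMH-like clusters 0 passed, with 0 at an unadjusted p under 0.05. With 126 splits, a lone changed share could not have passed the adjustment in either set. Cluster 41 made up 20.3 ± 4.95% of VMH-like neurons in lactating and 11.7 ± 5.91% in virgin libraries (exact permutation p = 0.0635, adjusted p = 0.423), and cluster 17, the other Esr1-rich cluster, 0% and 16.2 ± 14.6% (exact permutation p = 0.0873, adjusted p = 0.423). Genes that differed with lactation separate these clusters, so neither share is read as a change in cell number. The share of neurons that were VMH-like ran from 5.51% (lactating control replicate 1) to 35.4% (lactating control replicate 2). Cells with VMH markers and under 0.5 of the median UMI count of neurons, left out of these classes, made up 25.52% of neurons in lactating control replicate 1 and 7.37% to 13.75% elsewhere. The largest cluster among them, cluster 7 (2205 cells), was led by Pmch, Gm42418 and AY036118. No Nr5a1 or Fezf1 level was asked for here, so these cells are not shown to be VMH neurons.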

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

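Of the tests in this part, those of a wrong label, of hormonal state, of a dissociation response, of a shared session and all counts of other splits were chosen after the results were seen; those of depth, of thinning, of the GABAergic mix and of RNA from other cells were written before.

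Among the shares of cell classes, 2 libraries stood far from the others of their state, where chance alone does so for about 1 in 20 groups. The shares of 12 cell classes and 10 VMH-like clusters were examined in each state, so some flags can arise by chance. Flags of the same library are not independent. The gap of virgin control replicate 1 to the next library was 0.72 of the range of the 5 virgin libraries for endothelial cells (9.76% against 5.11% in the nearest library), 0.734 for fibroblast-like cells (0.64% against 0.43%) and 0.721 for mural cells (3.22% against 1.95%). For unnamed cells the gap of virgin nonaggressive replicate 3 was 0.964 of the range (33.39% against 2.78%), and lactating aggressive replicate 3, collected in the same session, had 27.5%. No biological explanation of these shares was tested.

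The genes that fell most in lactating Esr1-rich neurons also varied among the 9 non-lactating libraries, with mean log2 CPM of 2.39 in virgin nonaggressive replicate 3, 3.49 in virgin mating replicate 1, 3.50 in post-lactating control replicate 2 and 5.19 to 6.46 in the others. Of the Esr1-rich cells, cluster 17 held 0%, 12.97% and 8.62% in the named libraries, in that order, and 25.71% to 93.12% in the others. Fallen genes (Rasl11a, Samd9l, Gadd45a) lead cluster 17, so the mix of clusters 17 and 41 cannot be told apart from their level. For a lactating library carrying a virgin label, virgin nonaggressive replicate 3 held the 8 named risen genes at a median of 0.265 of the lowest lactating library. These genes were named with that library counted as virgin, so a low ratio is partly built in. All of them also passed in the fit without it, so the ratio argues against a wrong label for these genes alone. The split that placed this library with the lactating ones called 793 genes, against 398 for the real labels. Depth per cell cannot be told apart, because the correlation with median UMIs was -0.212 with a 95% interval from -0.768 to 0.526 over 9 libraries. Hormonal state that differs between the non-lactating animals, such as the estrous cycle, may contribute: Pgr in the separate Tac2-rich cluster 18 correlated with the level of the fallen genes (r = 0.683, permutation p = 0.0418, adjusted p = 0.0837 over 2 relations, rho = 0.483, permutation p = 0.194, and r = 0.595 without the 2 most extreme libraries). Of these 9 libraries 4, among them those highest and lowest in the fallen genes, had 7 to 18 cells of cluster 18, under the limit of 20 used elsewhere, and the 5 others were not tested on their own, so this stays open, as the labels used here give no cycle stage.

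Immediate early genes rose in Esr1-rich neurons after mating, with a median log2 fold change of 1.39 against the nonaggressive group. A dissociation response shared by all cells is argued against, as the highest median in 6 other classes was -0.0449 for that comparison, in astrocytes. Fewer UMIs in the mating libraries are argued against too, since thinning every library to the smallest total left a median of 2.02 over the 12 genes still measured (2.06 before thinning), and so is the shared session as the whole cause, since with session as a block the median was 1.67 and 3 members rose over all genes, although the list's call was then lost with an estimated correlation (adjusted p = 0.165) and by fry (adjusted p = 0.0625). The lower mitochondrially encoded genes of the mating libraries and the dependence on mating replicate 1 stay open. Mating replicate 2 also had a low share of astrocytes with a Xist UMI (60.1%), and what this means for the comparison was not tested. Activity that follows mating may be what the genes record, a hypothesis from 2 libraries.

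Of the genes that rose in lactating GABAergic neurons, several lead a single cluster, so a different mix of clusters could raise them. With a fixed weight for each cluster in all libraries the median log2 fold change of the 54 genes was 1.03, against 1.11 pooled, which argues against the mix as the whole cause. For Foxq1 it was 2.30 against 2.96, and for Adgrg6 1.73 against 2.36. RNA from other cells is argued against by a median of 0.151 in astrocytes of the same libraries over the 41 genes tested in both, where the GABAergic median was 1.24. Lactation may change transcription within GABAergic clusters, as a hypothesis from the same data.

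State labels were also given to the libraries in all 60 ways that keep the behaviours. In Esr1-rich neurons 2 of the 60 splits, the real one included, called at least the real 398 genes, so chance can be excluded at the 5% level for splits that do not keep collection sessions together. The highest other split called 793, and placed virgin nonaggressive replicate 3 with the lactating libraries; the next called 21. In GABAergic neurons 1 of 60, the real split, reached 57 genes, with 1 in the highest other, so chance can be excluded in that sense. The splits that swap labels only within sessions number 8, too few for a share under 0.05. The highest other of these called 0 genes in both classes. In endothelial cells 13 of 60 reached the real 1 (highest other 34), so chance cannot be excluded. A real count of 0 is reached by all 60 splits whatever the data, so in astrocytes (highest other 6), oligodendrocytes (144), oligodendrocyte precursors (450) and microglia (223) their number says nothing about chance. The splits with 144, 450 and 223 genes point to a structure of the samples: each placed lactating control replicate 1, virgin control replicate 1 and virgin nonaggressive replicate 1 together, and those of oligodendrocytes and microglia set the libraries of the first 2 collection sessions against later ones. With session as a block the real comparison gave 0 genes in oligodendrocytes, 2 in precursors and 1 in microglia.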

How the results depend on the processing

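Of the settings in this part, those with low-UMI clusters added and with cluster 41 alone were chosen after seeing the data. Over all settings, 528 of the values that answer a comparison kept their direction and side of the threshold or stayed within their limits, 101 moved, 1 was weaker, 1 stronger and 1 reversed. Of the values for single named genes 7610 stayed the same, 324 were weaker, 95 stronger and 2 reversed, the last being Mad2l1 (0.479) and Col12a1 (0.539) within cluster 41. Cluster 41 alone leaves out the other Esr1-rich cluster, whose leading genes fell in lactation, so these 2 changes of sign decide little. Except where the setting has fewer libraries or cells, the cause was not tested. DESeq2 size factors, no doublet removal, a higher minimum of detected genes, low-UMI clusters added, fry, logit shares, fewer cells per library and other cluster resolutions moved none of the values they were applied to. Of these, fry was applied to gene lists alone, logit to cell shares alone, and other resolutions to VMH-like cluster shares alone. Fewer cells per library were tried only for the immediate early gene list within clusters. Counts of changed genes were therefore not tested against these 4 settings.

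Without the low-count filter the calls in Esr1-rich neurons numbered 1042 for lactating against virgin (995 of them genes that pass the filter), 82 (79) and 409 (404) for post-lactating against virgin and against lactating, 26 (24), 32 (29) and 84 (83) for aggressive against control, aggressive against nonaggressive and nonaggressive against control, and 335 (329), 172 (167) and 208 (201) for mating against control, mating against nonaggressive and nonaggressive against control. In the other classes they were 160 in GABAergic neurons, 11 in astrocytes, 40 in oligodendrocytes, 22 in precursors, 26 in microglia and 40 in endothelial cells. DESeq2 gave 47 calls for post-lactating against lactating, 1 for lactating nonaggressive against control, 69, 12 and 18 for the 3 virgin comparisons in that order, and 135, 5, 3 and 2 in GABAergic neurons, astrocytes, oligodendrocytes and endothelial cells.

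With session as a block lactating against virgin gave 738 calls in Esr1-rich neurons, 137 in GABAergic neurons, 2 in precursors, 1 in microglia and 2 in endothelial cells. That block could not be fitted for contrasts whose groups share no session, among them those with post-lactating libraries. All 7 lactating against all 7 virgin libraries gave 1076 calls in Esr1-rich neurons, 254 in GABAergic neurons, 3 in astrocytes, 2 in oligodendrocytes, 1 in precursors, 7 in endothelial cells and 2 VMH-like cluster shares. Lactating control against virgin control alone gave 77, 1 and 0 calls in Esr1-rich neurons, GABAergic neurons and endothelial cells, where fewer libraries enter. Fits of only the groups compared gave 35 calls in GABAergic neurons, 0 in endothelial cells, and 90.9% of genes with the same direction after lactation.

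Barcodes with Slc17a6 and Esr1 UMIs gave 217 calls for lactating against virgin, 12 for post-lactating against lactating, 1 and 0 for mating against control and nonaggressive, an immediate early gene median of 0.494 for virgin nonaggressive against control, and 36.4% of genes with the same direction after lactation. Cluster 41 alone gave 163, 38, 10 and 3 calls for those first 4 comparisons. With an estimated correlation the immediate early gene list after mating kept its median of 1.743 against controls at an adjusted p of 0.0795. With at least 50 cells per library 1 cluster had a changed immediate early gene list.

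The replicate numbers do not pair the libraries. Of 8 pairs with the same number and session 5 had a correlation of deviations over 0.1 (0.0126 to 0.221), and of 35 with the same number from other sessions 6 did (-0.156 to 0.455). Not every library correlated best with one of its own number. Outside the 8 pairs the libraries share only a number. A replicate block gave 696 calls for lactating against virgin, 16 for mating against control and 334 (144 rises and 190 falls), in place of 74, for lactating against virgin nonaggressive libraries.

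Leaving out each library in turn, with a lone library of a group assumed to vary like the others, the calls in Esr1-rich neurons ran from 137 to 826 for lactating against virgin, 0 to 0 and 0 to 37 for post-lactating against virgin and lactating, 0 to 0, 0 to 1 and 0 to 0 for the lactating behaviours in the order above, and 0 to 19, 0 to 10 and 0 to 2 for the virgin ones. They ran from 20 to 67 in GABAergic neurons, 0 to 1 in astrocytes and microglia, 0 to 0 in oligodendrocytes and precursors, and 0 to 2 in endothelial cells. Immediate early gene medians ran from 0.263 to 0.459, -0.0683 to 0.258 and 0.141 to 0.511 in lactating comparisons, and from 0.872 to 2.27, 0.976 to 2.11 and -0.438 to 0.218 in virgin ones, the last passing the test without virgin control replicate 1 (-0.179). Clusters with a changed list ran from 0 to 2, and the same direction after lactation from 38.3% to 72.5%. Changed shares stayed at 0, but with 126 splits or fewer a lone changed share cannot reach an adjusted p under 0.05. That 0 therefore says little about stability.

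At the depth and number of libraries here, the comparisons of behaviours and those after lactation recovered 25.4% to 53.7% of genes simulated with a 2-fold change in Esr1-rich neurons, so changes of that size can be missed.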

Other observations

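Lactating and virgin females were also compared within 39 single clusters of the cells classed as neurons, of which 16 had 0 genes called by edgeR, among them VMH-like clusters 0 and 1, and VMH-like clusters 3 and 54 had 1 each. Some of the 39 were led by genes of other cells, such as cluster 39 (C1qb, C1qa, C1qc) and cluster 37 (Slc1a3, Slc4a4, Gm3764). Another was cluster 8 (Hbb-bs, Hcrt, Hba-a1), which is among the 16. These cluster tests, the choice of the genes in them and the test of Xist yield were made after seeing the data. In clusters 18 and 22 the virgin control group was replicate 2 alone, as replicate 1 had 7 and 10 cells, under the limit of 20. In cluster 2 the lactating control group was a lone library too. Each lone library weighed as much as the whole nonaggressive group of its state and was assumed to vary like the others. In cluster 22, a GABAergic cluster led by Slc18a2, Gm4847 and Coch that also carries the dopamine genes Th and Slc6a3, 355 genes rose and 143 fell of 11267 (n = 4 lactating against n = 4 virgin libraries; 1621 at an unadjusted p under 0.05 and 336 by DESeq2). Npy, neuropeptide Y, rose from 15.3 ± 19.8 to 975 ± 196 CPM (log2 7.01, adjusted p = 3.69e-06) and Penk, the enkephalin precursor, from 341 ± 135 to 1532 ± 114 CPM (log2 2.64, adjusted p = 4.67e-06). Cartpt, another peptide precursor, fell from 1793 ± 510 to 278 ± 142 CPM (log2 -2.40, adjusted p = 0.000818), while Th, the rate-limiting enzyme of dopamine synthesis, stood at log2 0.23 (adjusted p = 0.672). Fos rose from 28.7 ± 27.4 to 398 ± 243 CPM (log2 4.56, adjusted p = 0.00117) and Egr1 from 44.9 ± 37.0 to 239 ± 108.3 CPM (log2 2.86, adjusted p = 0.00226). Of 23 immediate early genes 14 rose and 1 fell there, or 16 and 2 adjusted over the list alone (median log2 2.86, camera adjusted p = 2.80e-11, but adjusted p = 0.196 with an estimated correlation).

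In cluster 18 (Tac2, Nr5a2, Nr4a2), a neuron cluster rich in the neurokinin B precursor Tac2, 275 genes rose and 539 fell of 11167 (n = 4 against n = 3; 2121 at an unadjusted p under 0.05 and 593 by DESeq2). Pgr fell from 379 ± 120 to 96.8 ± 43.1 CPM (log2 -1.79, adjusted p = 8.28e-05) and Pdyn, the dynorphin precursor, from 348 ± 90.05 to 53 ± 43.5 CPM (log2 -2.77, adjusted p = 6.08e-06), while Tac2 stood at log2 0.04 (adjusted p = 0.938). Nov, a secreted matrix protein, rose from 1.73 ± 1.33 to 207 ± 97.9 CPM (log2 6.74, adjusted p = 4.50e-07). In VMH-like cluster 4 (Dlk1, Arhgap36, Pcdh11x) 131 genes rose and 54 fell of 12054, with Pappa from 25.4 ± 7.88 to 101 ± 25.5 CPM (log2 2.02, adjusted p = 2.13e-05) and Tacr3, a tachykinin receptor, at log2 3.29. Its sterol synthesis list fell (median log2 -0.42, camera adjusted p = 3.51e-14, and adjusted p = 0.00193 with an estimated correlation), with 2 of 17 members down over all genes and 11 adjusted over the list alone. In VMH-like cluster 2 (Necab1, Adarb2, Npy2r) 51 genes rose and 15 fell of 12376 (n = 3 against n = 5), again with Tacr3 (log2 2.94), Pappa (log2 1.55) and Maml3 (log2 2.02) up and Pgr (log2 -1.02) down. Whether these changes differ between clusters was not tested. Cluster 18 was tested without virgin nonaggressive replicate 3 (18 cells) and virgin control replicate 1 (7 cells). With unadjusted totals these had 189 and 533 CPM of Pgr and 235 and 341 CPM of Pdyn, in that order. The virgin libraries kept had 242 to 441 CPM of Pgr and 248 to 401 CPM of Pdyn. The first library left out was thus nearer the lactating level than those kept, and its effect on the counts was not tested.

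In virgin mating replicate 2, 60.1% of astrocytes had a UMI of Xist, the RNA of the inactive X chromosome, against 88.5% to 98.5% in the other 15 libraries. Of its neurons 43.4% had one, against 54.1% in lactating control replicate 1 and 81.0% to 96.9% elsewhere. Cells with a single X chromosome may account for it. If so, astrocytes of that library without a Xist UMI should hold genes that escape X inactivation (Kdm6a, Kdm5c, Ddx3x, Eif2s3x) at a lower level than those with one. In this test, written before the result was seen, the ratio was 0.76, between the bounds set for and against, and 0.753 (95% interval 0.696 to 0.815) at matched depth, where post-lactating control replicate 2 had 0.654 (0.351 to 1.217) from 12 astrocytes without a Xist UMI. A lower yield of Xist alike in all cells would leave the matched ratio near 1, which the interval argues against. Cells with a single X chromosome stay open. Y-linked genes had 10 of 12586042 UMIs in these cells, against 0 to 5 UMIs in the astrocytes of each other library.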
